A study of Mus musculus with 16 samples.

How the data were processed

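The data are ATAC-seq libraries of sorted mouse mTECs, 60000 cells per Tn5 reaction per the labels. Cells were negative for DAPI and CD45 and positive for EpCAM and UEA with low Ly51, and were split by MHC class II level. The authors deposited a single table with a signal value for each of 250313 regions in 16 libraries, and each of its 16 columns matched the description of 1 library. The names begin with NOCRE for Brg1+/+, BRG for Brg1-/-, WT for Aire+/+ and AIRE for Aire-/-. Bowtie2, MACS2 and the mm9 build are named in the submitters' processing notes, without versions. How the authors defined the regions, shifted reads for the Tn5 offset, removed duplicates and scaled the libraries is not given in the sources used here. The signal values as deposited are not whole counts, and no whole reads could be recovered from them, so depth per library is unknown and no count model was used. The highest value and the 99th percentile were nearly equal in all libraries while medians ranged from 8.51 to 19.8, so levels are comparable between libraries only as far as the authors' scaling made them so. A 0 was listed for 10165 values in 3 libraries.

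Region names hold a chromosome, a start and an end; the start was taken as counted from 0, as in BED files, and positions are printed counted from 1. The end of the last region on chromosome 1, 197135460, was in keeping with mm9. The gene table at hand belongs to another assembly, so regions were not linked to genes: the 17 gene lists fixed in advance and a check of accessibility at the Aire and Smarca4 loci were not run, and the genotypes rest on the labels alone. Whether a region lies in a promoter, exon or intron was not analysed here.

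Groups were taken from the labels. Signal was analysed as log2(signal + 1), so a fold change is on that scale and understates the change of low regions. Regions with a mean over all libraries under the 10th percentile (7.48) were left out, which removed 25032 and kept 225281. limma 3.58.1 in R 4.3.3 fitted 1 mean for each of the 8 groups over all 16 libraries, with 8 residual degrees of freedom, and moderated the variances with a trend and robust settings. Regions were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, within each of 12 contrasts. These were each knockout against its wild type per sort, mTEChi against mTEClo per genotype, the 2 interactions, and Aire+/+ against Brg1+/+ per sort. The contrasts, their fit, the rule for named regions and most alternatives were fixed before the data were examined.

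Named regions were chosen per contrast and direction as the 10 with the largest log2 fold change among those called, with a mean at or above the median region and both libraries of 1 group above both of the other (5 for an interaction); the text gives a subset, and "largest" refers to regions that meet this rule. Where no SE or p follows a named region, it passed the same threshold. Overlaps of calls were set against n1 × n2 / N for independent lists and tested with Fisher's exact test; regions are not independent replicates, so those p-values are descriptions. Classes of regions, which were planned with their median log2 fold changes and processing alternatives, were the limma calls of mTEChi against mTEClo in the wild type of the other cohort. Their shifts are differences of median log2 fold change from unclassed regions, tested over 12 combinations with limma camera, at a preset correlation of 0.01 and with an estimated correlation, and with limma fry; camera and fry were added after the data were seen, and the value with an estimated correlation decided each call. Clustering was tested as the share of calls with another call of the same direction within 50 kb, against 1000 seeded shuffles of the calls over tested regions. The limits of the chromosome 2 block were those of the longest run of regions called lower in Aire+/+ than in Brg1+/+ mTEChi with gaps of at most 50 kb.

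The limma procedure was tested on simulated data for all 225281 regions, with normal errors and 200 regions changed by log2 fold changes of 1, 2 or 3. Errors had the moderated spread of each region, scaled by 1 factor per group, and all groups shared the mean of a region. The changed regions, 66 or 67 per fold change, were drawn from those at or above the median mean log2 signal. Recovery at regions of lower signal was not measured. In the comparison of Aire-/- with Aire+/+ it recovered 1.49%, 37.3% and 56.1% of them in mTEChi and 1.49%, 22.4% and 54.5% in mTEClo. For Brg1 the shares were 5.97%, 20.9% and 59.1% in mTEChi and 1.49%, 19.4% and 51.5% in mTEClo. Alternatives changed 1 choice at a time: a pseudocount of 0.5 or 5, no filter or a filter at the 50th percentile, quantile normalization, cyclic loess normalization, re-centring, fewer libraries in the fit, a replicate block, quality weights (which came out equal for both libraries of each group), leaving out chromosome X, a minimum absolute log2 fold change of 1, and leaving out each library in turn. With 1 library left in a group, limma assumes that it varies like the other groups. Tables were read with data.table (version 1.17.8) and figures drawn with matplotlib 3.10.9 in Python 3.11.15.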

Results

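Chromatin accessibility was measured by ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into open DNA, in medullary thymic epithelial cells (mTECs) of 4-week-old mice, all labelled C57BL/6. These cells transcribe many genes that are otherwise restricted to single peripheral tissues, which exposes developing T cells to the encoded antigens. Aire is a nuclear regulator needed for much of that transcription, and Brg1 is the ATPase of the SWI/SNF chromatin remodelling complexes. mTECs were sorted by surface MHC class II into a high fraction (mTEChi), where most Aire protein is found, and a low fraction (mTEClo). The 16 libraries made 8 groups of 2: Aire+/+, Aire-/-, Brg1+/+ and Brg1-/-, each as mTEChi and as mTEClo. The labels do not say whether the 2 libraries of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical. They also do not say whether the Aire and Brg1 lines differ in background. The descriptions of the Brg1+/+ libraries read NOCRE, so Brg1-/- and Brg1+/+ may also differ in the presence of Cre.

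Signal was given for 250313 regions of 500 bp on 19 autosomes and chromosome X, in mm9 coordinates. The median signal per library lay between 8.51 and 19.8, while the 99th percentile lay between 213.7 and 217.3 in each library. Read depth is not recorded with these values, so no counting interval could be given. The mTEChi and mTEClo sorts separated on the first principal component, which held 32.8% of the variance. All 8 mTEChi libraries scored between 188.4 and 330.4 on it, and all 8 mTEClo libraries between -356.2 and -189.9. Across regions, which are not independent replicates, log2 signal correlated between the 2 libraries of a group with a median Pearson r of 0.769. The lowest such value, 0.540, belonged to Aire+/+ mTEChi, whose replicate 2 had a median r of 0.543 with the other mTEChi libraries. The 2 libraries of a group gave 0.540 to 0.770 in mTEChi and 0.768 to 0.816 in mTEClo. Libraries of different groups within a sort correlated with a median r of 0.606 in mTEChi and 0.768 in mTEClo. The replicate values therefore do not show a grouping by genotype in mTEClo. In mTEChi they do not show it for each group either. The values of Aire+/+ (0.540) and Brg1-/- (0.596) lay below the median of 0.606 between groups. Libraries of different sorts correlated with a median r of 0.507.

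The wild-type sorts were compared first, to ask which regions distinguish mTEChi from mTEClo. In Aire+/+ mice, 11581 regions were more accessible in mTEChi and 8225 in mTEClo, together 8.79% of the 225281 regions tested. In Brg1+/+ mice, the numbers were 20751 and 8458, or 13.0%. The largest rise in Aire+/+ was on chromosome 5 from 67792110 to 67792609, where signal was 110.1 ± 41.2 in mTEChi and 1.24 ± 0.85 in mTEClo (SD, n = 2), a log2 fold change of 5.63 with an SE of 0.70 (adjusted p = 4.53e-06). In Brg1+/+ it was on chromosome 14 from 24204867 to 24205366, with 91.4 ± 22.5 in mTEChi and 0.50 ± 0.16 in mTEClo (log2 fold change 5.93, SE 0.72, adjusted p = 3.83e-06). A region of chromosome 19 from 36180171 to 36180670 gave 114.9 ± 0.25 against 1.69 ± 1.88 in Brg1+/+ (log2 fold change 5.63).

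Regions higher in mTEClo reached similar differences. On chromosome 12 from 74549410 to 74549909, the Aire+/+ mTEClo libraries held 69.97 and 76.66, against 3.08 in one mTEChi library and a listed 0 in the other (log2 fold change -5.20, adjusted p = 1.57e-06). On chromosome 2 from 178363129 to 178363628, signal in Brg1+/+ was 2.00 ± 0.66 in mTEChi and 120.0 ± 6.81 in mTEClo (log2 fold change -5.35, SE 0.56, adjusted p = 4.77e-07). On chromosome 13 from 103002300 to 103002799 it was 11.7 ± 7.22 against 305.4 ± 38.1 (log2 fold change -4.71, adjusted p = 2.89e-08). Both wild types called 6746 of the same regions higher in mTEChi, where independent lists would share 1066.7, and 3983 higher in mTEClo, where they would share 308.8. Leaving out 1 library took these numbers to 3025 to 4625 and 1550 to 3240, and quantile normalization took the first to 3769. Regions called in opposite directions numbered 0 and 6 by limma. Across regions, the mTEChi against mTEClo fold changes of the wild types correlated with Pearson r = 0.59 and Spearman rho = 0.56.

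The balance of mTEChi-higher to mTEClo-higher calls depended on the scaling of the libraries. The rescalings used here bring the overall median to about 0 by construction, so they do not test the excess. The median log2 fold change over all regions was 0.16 in Aire+/+ and 0.42 in Brg1+/+, and the mTEChi-higher share of calls went from 58.5% to 45.2% in Aire+/+ and from 71.0% to 43.9% in Brg1+/+ under quantile normalization, with 48.8% and 48.0% after cyclic loess and 48.4% and 42.2% after re-centring on the median. Leaving out 1 library lowered the Aire+/+ count of 19806 to 12816 without mTEChi replicate 2, to 10853 without mTEClo replicate 1 and to 6319 without mTEClo replicate 2, and the Brg1+/+ count of 29209 to 17031 and 14737 without mTEChi replicates 1 and 2 and to 14200 and 11705 without mTEClo replicates 1 and 2.

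**Figure D1:**
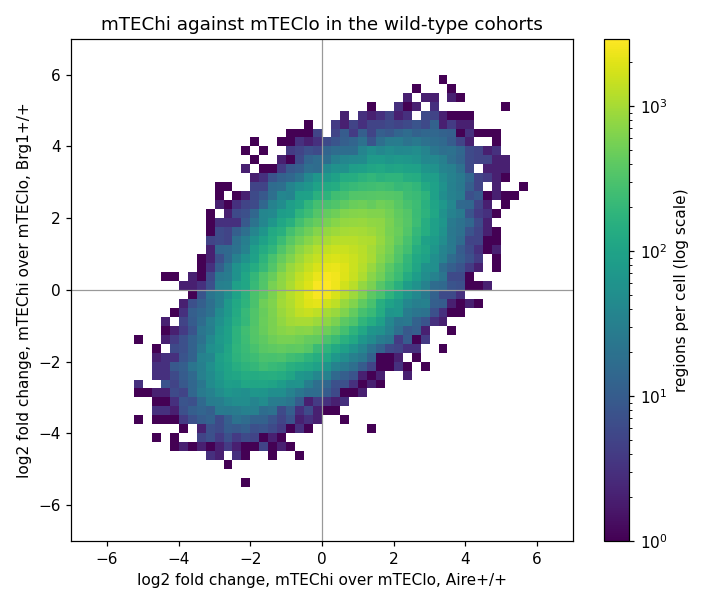
Log2 fold change of mTEChi over mTEClo per region in Aire+/+ (horizontal axis) and Brg1+/+ (vertical axis), with colour giving the number of regions per cell on a log scale. The cloud runs along the diagonal (Pearson r = 0.59 across regions), with medians of 0.16 in Aire+/+ and 0.42 in Brg1+/+ that went to near 0 on rescaling.

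The same sorts were compared in the knockouts, to ask whether the distinction between them holds without Aire or Brg1. Aire-/- mice had 16106 regions higher in mTEChi and 9498 higher in mTEClo, and Brg1-/- mice had 14885 and 3383. The largest rise in Aire-/- was on chromosome 2 from 30974510 to 30975009, with 113.4 and 125.0 in the mTEChi libraries against 1.80 and a listed 0 in mTEClo (log2 fold change 6.17, adjusted p = 1.60e-07). The largest fall in Aire-/- was on chromosome 4 from 153587611 to 153588110, with 1.02 ± 0.45 in mTEChi and 91.75 ± 6.21 in mTEClo (log2 fold change -5.53, adjusted p = 3.17e-07). In Brg1-/-, a region of chromosome 15 from 50582490 to 50582989 rose most (57.2 ± 8.13 against 0.48 ± 0.066, log2 fold change 5.29), and a region of chromosome 11 from 41751294 to 41751793 fell most (1.95 ± 0.076 against 92.1 ± 16.8, log2 fold change -4.97, adjusted p = 2.15e-09). All 4 genotypes called 3030 of the same regions higher in mTEChi and 1338 higher in mTEClo, against 5.04 and 0.20 for independent lists.

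At the regions that Brg1+/+ called mTEChi-higher, the median log2 fold change between the sorts was 1.48 in Aire+/+ and 1.73 in Aire-/-, and at those it called mTEClo-higher it was -1.54 and -1.64. At those that Aire+/+ called mTEChi-higher, it was 1.96 in Brg1+/+ and 1.63 in Brg1-/-, and at those that Aire+/+ called mTEClo-higher it was -1.51 in Brg1+/+ and -0.85 in Brg1-/-. Relative to unclassed regions, these Brg1 values were 1.56 and 1.02 at mTEChi-higher regions and -1.91 and -1.46 at mTEClo-higher regions. The median over all regions was 0.096 in Aire-/- and 0.62 in Brg1-/-, and the mTEChi-higher share of calls went from 62.9% to 51.4% in Aire-/- and from 81.5% to 35.8% in Brg1-/- under quantile normalization, to 45.3% after cyclic loess and 31.7% after re-centring in Brg1-/-. Without 1 library, the Aire-/- count of 25604 went to 9398 and 12076 (mTEChi replicates 1 and 2) or 12167 and 9021 (mTEClo replicates 1 and 2), and the Brg1-/- count of 18268 to 9680 and 5945 or 6550 and 8025 in the same order.

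Aire-/- was then compared with Aire+/+ within each sort, to ask how loss of Aire moves accessibility. In mTEChi, 25 regions rose and 22 fell, and no call was made in mTEClo, but the test was stricter in mTEClo (below). The largest rise was on chromosome 2 from 175001257 to 175001756, from 2.30 ± 1.12 in Aire+/+ to 52.1 ± 21.9 in Aire-/- (log2 fold change 3.99, SE 0.65, adjusted p = 0.0344). A region of chromosome 18 from 11731539 to 11732038 rose from 2.74 ± 1.27 to 47.5 ± 7.39, and one of chromosome 1 from 31115691 to 31116190 rose from 6.58 ± 4.02 to 80.9 ± 14.2. The largest fall was on chromosome 15 from 37649762 to 37650261, from 44.8 ± 18.9 to 3.19 ± 3.38 (log2 fold change -3.67, SE 0.62, adjusted p = 0.0368). On chromosome 4 from 153587611 to 153588110, the region with the largest fall from mTEClo to mTEChi in Aire-/-, signal in mTEChi fell from 22.6 ± 7.56 to 1.02 ± 0.45 (log2 fold change -3.52). A region of chromosome 2 from 19501343 to 19501842 fell from 38.7 ± 4.37 to 3.26 ± 1.47.

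The Aire-/- calls in mTEChi had a median absolute log2 fold change of 2.80. Of the 22 regions that fell, 17 had the same sign in mTEClo, with a median log2 fold change there of -0.22, where all regions of the same classes would give 12.3. Of the 25 that rose, 17 did, with a median of 0.091, where the classes would give 11.98. These counts were not tested, since the regions were measured in the same libraries, and none of these 47 regions had the same sign with an unadjusted p under 0.05 in mTEClo by limma. In mTEClo, limma called 0 regions at an adjusted p under 0.05 and 5632 at an unadjusted p under 0.05, which is 2.50% of those tested, against 1.09% of unchanged regions in simulated data; the smallest adjusted p was 0.709. Quality weights, which came out equal for both libraries of each group, gave 12 calls in mTEClo, and leaving out 1 mTEClo library gave 25 without Aire+/+ replicate 1, 0 without Aire+/+ replicate 2, 5 without Aire-/- replicate 1 and 1 without Aire-/- replicate 2.

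The mTEChi count depended on which libraries were fitted and how. It was 2243 without Aire+/+ replicate 1, 96 without Aire+/+ replicate 2 and 21 without Aire-/- replicate 1, and limma called 0 regions with only the Aire libraries in the fit or with these weights (0.58 for both Aire+/+ mTEChi libraries), beside 22934 at an unadjusted p under 0.05 in the fit of all libraries, or 10.2%. In simulated data with the spreads of these groups, 8.03% of unchanged regions passed that unadjusted threshold. The same test recovered 37.3% of the regions changed by 2 on the log2 scale, which were drawn at or above the median signal. It made 11 false calls in this comparison, so single calls carry less weight than their adjusted p states. The fit used 1 variance per region for both sorts, and 1.09% of unchanged regions passed in simulated mTEClo data. With quality weights, limma called 0 regions in mTEChi and 12 in mTEClo. The counts therefore do not show that loss of Aire acts more in mTEChi.

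Brg1-/- was compared with Brg1+/+ in the same way. In mTEChi, 33 regions rose and 25 fell. The largest rises were on chromosome 15 from 85041109 to 85041608, from 1.44 ± 0.42 to 35.0 ± 5.95 (log2 fold change 3.88, SE 0.73, adjusted p = 0.0458), and on chromosome 7 from 123788638 to 123789137, from 4.07 ± 3.65 to 61.3 ± 2.77 (log2 fold change 3.84). On chromosome 17 from 81415043 to 81415542, signal rose from 3.02 ± 1.08 to 49.5 ± 2.40 (adjusted p = 0.00295). The largest fall was on chromosome 9 from 98238481 to 98238980, from 44.1 ± 7.57 to 2.06 ± 0.095 (log2 fold change -3.87, SE 0.49, adjusted p = 0.000587). On chromosome 11 from 41751294 to 41751793, which also had the largest fall from mTEClo to mTEChi in Brg1-/-, signal fell from 35.5 ± 16.3 to 1.95 ± 0.076 (log2 fold change -3.55, adjusted p = 1.32e-05). On chromosome 7 from 71724232 to 71724731 it fell from 60.6 ± 0.25 to 5.75 ± 5.79.

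Of the 25 regions that fell in Brg1-/- mTEChi, 20 had the same sign in mTEClo, with a median log2 fold change there of -0.28, where all regions of the same classes would give 14.3, and 6 of them had an unadjusted p under 0.05 in mTEClo by limma. On chromosome 11 from 41751294 to 41751793, the mTEClo libraries held 255.3 and 203.9 in Brg1+/+ and 80.2 and 104.0 in Brg1-/-. Of the 33 that rose, 20 had the same sign, where the classes would give 15.7, and 0 of them had an unadjusted p under 0.05 in mTEClo by limma; neither count was tested. In mTEClo 1 region fell, on chromosome 6 from 122419207 to 122419706, from 45.8 ± 9.34 to 5.70 ± 0.65 (log2 fold change -2.79, SE 0.41, adjusted p = 0.0209), beside 13866 regions at an unadjusted p under 0.05, or 6.16%, against 3.30% of unchanged regions in simulated data. That call was lost when any 1 of the 4 mTEClo libraries was left out; the count was then 0 to 2.

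Over all regions, the median log2 fold change of Brg1-/- mTEChi was 0.22, and it went from 0.57 in the tenth of regions with the lowest mean signal to 0.020 in the tenth with the highest. After rescaling, which brings it to about 0 by construction, the overall median was -0.0023 (quantile), -0.017 (cyclic loess) and -0.031 (re-centring), so its sign depends on the scaling. In mTEClo it was 0.048. The mTEChi count of 58 became 101 without Brg1+/+ replicate 1, 340 without Brg1+/+ replicate 2, 217 without Brg1-/- replicate 1 and 159 without Brg1-/- replicate 2, with 316 of 340 calls higher in the one fit and 194 of 217 lower in the other. After quantile normalization it was 121, with 29 higher and 92 lower. It was 8 with quality weights, 3 with only the Brg1 libraries in the fit, and 0 by limma with only the 4 libraries compared, against 24090, or 10.7%, at an unadjusted p under 0.05 in the fit of all libraries; simulated data with these spreads gave 30 false calls and 8.62% of unchanged regions at an unadjusted p under 0.05. In mTEClo, quality weights gave 12 calls, and 3.30% of unchanged regions passed in simulated data. The counts therefore do not show that loss of Brg1 acts more in mTEChi.

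The regions that rose or fell were then set against the classes of regions that distinguish the sorts. To keep the fold changes of class and effect on separate libraries, the Brg1 effect was read at regions classed in Aire+/+ mice, and the Aire effect at regions classed in Brg1+/+ mice. The variance behind each class call still came from the fit of all 16 libraries. In Brg1-/- mice, accessibility was lower at the regions that mark each sort within that sort, relative to regions of neither class. In Brg1-/- mTEChi, the 11581 mTEChi-higher regions had a median log2 fold change of -0.16 against 0.25 at unclassed regions, a shift of -0.41 (limma camera, adjusted p = 0.0101 with an estimated correlation and 3.17e-07 with the preset one). In Brg1-/- mTEClo, the 8225 mTEClo-higher regions had a median of -0.44 against 0.065, a shift of -0.51 (adjusted p = 0.000937 with an estimated correlation), and 19.6% of them had a positive fold change.

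Each library of Brg1-/- lay below each library of Brg1+/+ in these measures. The mTEChi-higher regions stood above unclassed regions by 1.68 ± 0.055 in Brg1+/+ mTEChi and 1.07 ± 0.155 in Brg1-/- mTEChi, in log2 units (SD, n = 2). The mTEClo-higher regions stood above them by 2.44 ± 0.011 in Brg1+/+ mTEClo and 1.77 ± 0.187 in Brg1-/- mTEClo. In mTEChi, part of the difference came from unclassed regions, with library medians of 3.77 and 3.91 in Brg1+/+ and 4.10 and 4.46 in Brg1-/-. The mTEChi-higher medians were 5.49 and 5.55 against 5.27 and 5.42. In mTEClo, unclassed medians were 3.445 and 3.33 against 3.40 and 3.58, and mTEClo-higher medians were 5.89 and 5.76 against 5.30 and 5.22. Each class moved less in the other sort: the shift at mTEClo-higher regions in mTEChi was -0.083 (adjusted p = 0.734), and that at mTEChi-higher regions in mTEClo was 0.096 (adjusted p = 0.208). The difference between the sorts was itself tested. The Brg1-/- effect in mTEChi minus that in mTEClo was shifted by -0.48 at mTEChi-higher regions (adjusted p = 0.0101) and by 0.39 at mTEClo-higher regions (adjusted p = 0.00976), both by camera with an estimated correlation. By limma fry, this difference did not pass at mTEChi-higher regions (adjusted p = 0.111) and passed at mTEClo-higher regions (adjusted p = 0.00206).

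The shift of -0.41 became -0.23 against unclassed regions matched on signal, without a test, and -0.36 without Brg1+/+ mTEChi replicate 1 (adjusted p = 0.0569, with 0.00126 to 0.0166 over the alternatives that keep all libraries). By limma fry, which asks whether a class moves on balance without reference to other regions, the mTEClo-higher regions fell in mTEClo (adjusted p = 0.00206) and the mTEChi-higher regions did not pass in mTEChi (adjusted p = 0.157); at the mTEClo-higher regions in mTEChi, fry and the class median of 0.17 pointed up and camera pointed down, none past the threshold.

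**Figure D2:**
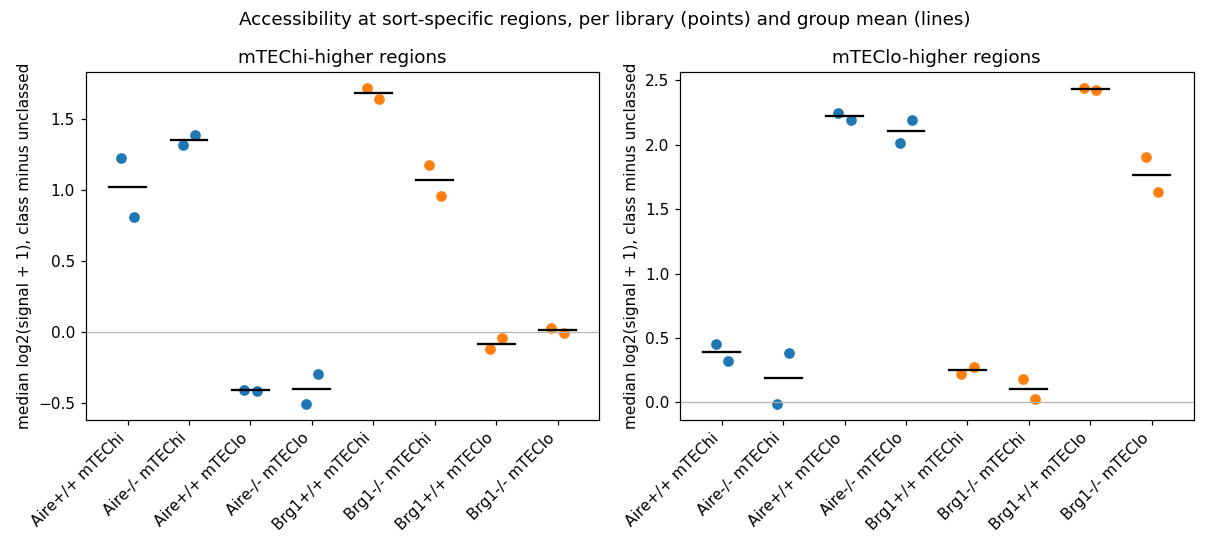
Median log2(signal + 1) of mTEChi-higher regions (left) and mTEClo-higher regions (right) minus that of unclassed regions, with 1 point per library and a line at each group mean of 2 libraries. Brg1-/- lies below Brg1+/+ at mTEChi-higher regions in mTEChi (1.07 against 1.68) and at mTEClo-higher regions in mTEClo (1.77 against 2.44). In mTEChi, part of the difference came from higher medians of unclassed regions in Brg1-/-.

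The shifts of Aire-/- at these classes did not pass the threshold with an estimated correlation. In Aire-/- mTEChi, the shift was 0.21 at the 20751 mTEChi-higher regions (adjusted p = 0.153 with an estimated correlation, 0.0167 with the preset one) and -0.13 at the 8458 mTEClo-higher regions (adjusted p = 0.0690 and 0.0167). In Aire-/- mTEClo, it was -0.031 at mTEChi-higher regions (adjusted p = 0.798 with an estimated correlation) and -0.12 at mTEClo-higher regions (adjusted p = 0.0688, with 0.0158 under the preset one). The mTEChi-higher regions stood above unclassed regions by 1.02 ± 0.294 in Aire+/+ mTEChi and 1.35 ± 0.050 in Aire-/- mTEChi (SD, n = 2). The Aire-/- effect in mTEChi minus that in mTEClo was shifted by 0.22 at mTEChi-higher regions (adjusted p = 0.170 with an estimated correlation) and by -0.024 at mTEClo-higher regions (adjusted p = 0.659). Of the regions called in Aire-/- mTEChi, 5 that rose and 11 that fell were mTEClo-higher, and 1 that rose was mTEChi-higher. In Brg1-/- mTEChi, 6 that rose and 8 that fell were mTEClo-higher, and none was mTEChi-higher, while 679 mTEChi-higher regions were lower and 230 higher at an unadjusted p under 0.05 by limma, together 7.85% of the class. The 1 region that fell in Brg1-/- mTEClo was mTEChi-higher; no mTEClo-higher region was called there, with 907 lower and 25 higher at an unadjusted p under 0.05, together 11.3%. Calls were spread unevenly between the mTEChi-higher and mTEClo-higher classes, with Fisher's exact p of 0.00926 for rises and 1.19e-06 for falls in Aire-/-, and 0.00512 and 0.000883 in Brg1-/-. The regions share libraries, so these p-values are descriptions and do not show that a knockout acts on 1 class. In mTEChi, mTEClo-higher regions passed an unadjusted p under 0.05 more often by limma. Their shares were 17.0% against 8.78% of mTEChi-higher regions in Aire-/- and 18.4% against 7.85% in Brg1-/-. In mTEClo the order was reversed in Aire-/-, with 0.72% of mTEClo-higher against 5.23% of mTEChi-higher regions. In Brg1-/- mTEClo the shares were 11.3% and 10.2%. The fit used 1 variance per region for both sorts, so these shares do not show that either knockout acts more on 1 class.

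The mTEClo-higher shift of Aire-/- passed the threshold in mTEChi under cyclic loess normalization (-0.23, adjusted p = 0.0164) and among regions at or above the median signal (-0.21, adjusted p = 0.0149), within a range of adjusted p from 0.0149 to 0.282 over the alternatives that keep all libraries. Without Aire-/- mTEChi replicate 2 it was -0.25 (adjusted p = 0.00913), and without Aire-/- mTEClo replicate 2 the shift in mTEClo was -0.17 (adjusted p = 0.0411). The shift in mTEClo also passed at a pseudocount of 5 (-0.11, adjusted p = 0.0381), among regions at or above the median signal (-0.13, adjusted p = 0.0396), after cyclic loess (-0.13, adjusted p = 0.0422) and with classes from Brg1-/- (-0.10, adjusted p = 0.0459), within a range of adjusted p from 0.0381 to 0.210 over the alternatives that keep all libraries.

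**Figure D3:**
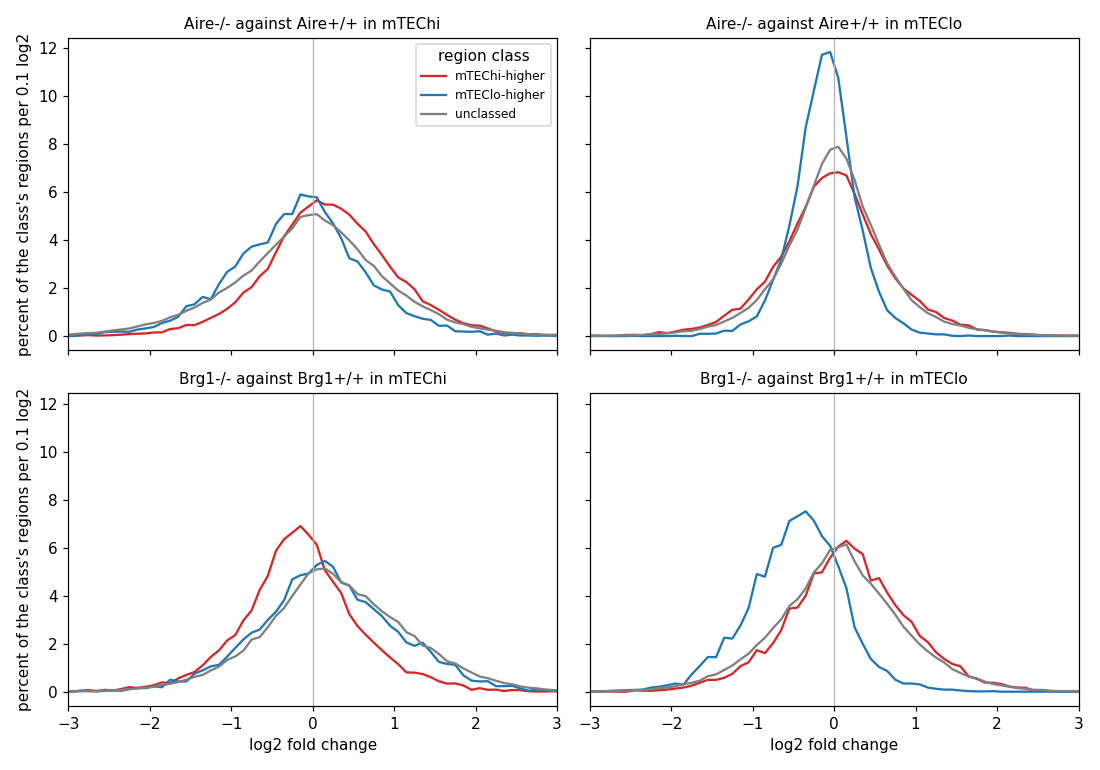
Distribution of log2 fold changes for each knockout and sort, as the percent of the regions of a class per 0.1 log2, for mTEChi-higher (red), mTEClo-higher (blue) and unclassed regions (grey). The red curve lies to the left of the grey one in Brg1-/- mTEChi (medians -0.16 and 0.25), and the blue curve in Brg1-/- mTEClo (medians -0.44 and 0.065).

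The effects of Aire and Brg1 were set side by side, to ask whether their loss moves the same regions. In mTEChi, none of the 47 regions called in Aire-/- was among the 58 called in Brg1-/-, in any of the 4 combinations of direction, where independent lists would share at most 0.0037; with so few limma calls this count holds little information, and 22934 and 24090 regions passed an unadjusted p under 0.05 (10.2% and 10.7%, against 8.03% and 8.62% of unchanged regions in simulated data). Across all regions, the fold changes correlated with Pearson r = -0.088 and Spearman rho = -0.084. The cohorts share no control library. Without Aire+/+ mTEChi replicate 2, r was -0.041; without Aire+/+ mTEChi replicate 1, 3 regions rose in both knockouts and 2 rose in Aire-/- and fell in Brg1-/-, and without Brg1+/+ mTEChi replicate 2, 1 region fell in Aire-/- and rose in Brg1-/-.

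Region by region, few tests showed that a knockout acted differently in the sorts. For Aire, 1 region passed, on chromosome 2 from 77823875 to 77824374, where the effect in mTEChi lay below that in mTEClo by a log2 difference of -5.43 (SE 0.78, adjusted p = 0.0150). Its signal was 18.1 and 24.5 in Aire+/+ mTEChi and 4.30 and 2.12 in Aire-/- mTEChi, while in mTEClo it was 1.21 and a listed 0 in Aire+/+ and 8.31 and 13.9 in Aire-/-, so the difference joins a lower value in mTEChi to a higher one in mTEClo that starts near 0. The region met the filter on mean signal through the Brg1 cohort, whose group means were 80.1 to 278.6, and the call was lost without replicate 2 of any of the 4 Aire groups. For Brg1, limma called 0 regions at an adjusted p under 0.05 (smallest adjusted p = 0.220), and 15980 passed an unadjusted p under 0.05, with 11603 for Aire; these are 7.09% and 5.15%, against 5.85% and 4.25% in simulated data with no change. The Aire count was 73 without Aire+/+ mTEChi replicate 1 and 2 without Aire+/+ mTEChi replicate 2, and the Brg1 count was at most 7, without Brg1+/+ mTEChi replicate 2.

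Finally, the wild types of the Aire and Brg1 cohorts were compared, as a measure of how far the cohorts differ apart from either mutation. Aire+/+ exceeded Brg1+/+ at 147 regions and lay below it at 205 in mTEChi, with 4 and 79 in mTEClo. Of these, 138 in mTEChi and 76 in mTEClo lay in 1 block of chromosome 2 from 77707854 to 77865218, which spans 157 kb and holds 167 tested regions. Signal there was higher in each of the 8 libraries of the Brg1 cohort than in each of the 8 of the Aire cohort at 158 of the 167 regions. The median signal of the block was between 4.30 and 8.45 in the Aire cohort and between 52.6 and 259.2 in the Brg1 cohort. The median ratio of the cohorts was 19.6, with quartiles of 15.4 and 23.1, while 17 regions within 200 kb on either side had a median ratio of 0.888. The region of the Aire interaction above lies in this block, as does 1 of the regions that fell in Aire-/- mTEChi, on chromosome 2 from 77861976 to 77862475 (log2 fold change -3.25, adjusted p = 0.0475).

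Outside the block, 214 regions in mTEChi and 7 in mTEClo differed between the wild types. The mTEChi count of 352 was 1608 without Aire+/+ replicate 1 and the mTEClo count of 83 was 35 and 24 without Brg1+/+ replicates 1 and 2; simulated data with these spreads gave 75 false calls in mTEChi and 0 in mTEClo. The median log2 fold change over all regions was 0.18 in mTEChi and 0.42 in mTEClo, and it went to near 0 after rescaling: -0.016, 0.0036 and 0.0034 in mTEChi and -0.0045, -0.019 and -0.022 in mTEClo after quantile normalization, cyclic loess and re-centring. Among regions at or above the median signal it was 0.24 in mTEClo.

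**Figure D4:**
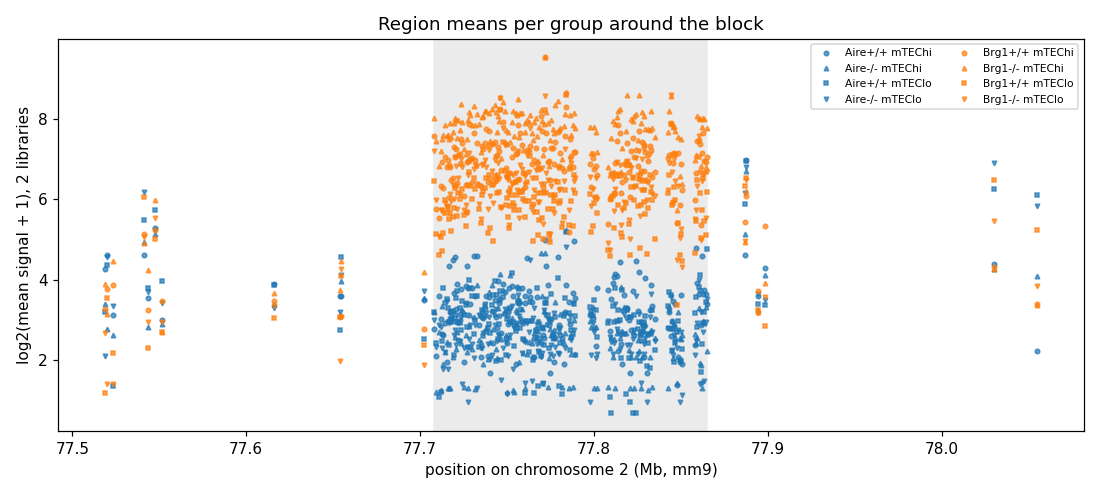
Log2(mean signal + 1) of each region per group, against position on chromosome 2 in Mb (mm9), with the block shaded and 200 kb shown on either side. The Brg1 cohort (orange) lies above the Aire cohort (blue) within the block, where the median ratio was 19.6, and the cohorts overlap outside it.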

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

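The tests of explanations and the camera and fry tests in this part were chosen after the data were seen, while the classes of regions, their processing alternatives and the test of single regions were planned. The effect of a knockout differed between mTEChi and mTEClo in 3 results, each by a test of the difference itself. The Aire-/- effect on chromosome 2 from 77823875 to 77824374 differed by a log2 value of -5.43, but that call was lost in 4 of the 8 fits that left out 1 library, namely replicate 2 of each Aire group, and in 4 other alternatives. It lies in the block described last and rests in mTEClo on values of 1.21 and a listed 0 against 8.31 and 13.9. The Brg1-/- effect differed by -0.48 at mTEChi-higher regions and by 0.39 at mTEClo-higher regions, both past the threshold by camera. By fry, only the difference at mTEClo-higher regions passed (adjusted p = 0.00206, against 0.111 at mTEChi-higher regions). These differences were not measured against unclassed regions matched on signal.

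Relative to unclassed regions, signal was lower at mTEChi-higher regions in Brg1-/- mTEChi and at mTEClo-higher regions in Brg1-/- mTEClo; a fall of the class on its own passed only in mTEClo (fry, adjusted p = 0.157 in mTEChi and 0.00206 in mTEClo). Cells of the other sort would have raised the other class by 1.01 in mTEChi and 0.82 in mTEClo, and the values were -0.083 and 0.096, with SDs of 0.138 and 0.133, which argues against mixing as the whole cause. Against unclassed regions matched on signal in Aire-/- mice, the shifts were still -0.23 (SD 0.036) in mTEChi and -0.41 (SD 0.044) in mTEClo. Unmatched they were -0.41 and -0.51. This argues against a weaker signal at all well-opened regions as the whole cause, though such a signal may account for part of the shifts. The 10th percentile of signal was higher in Brg1-/- than in Brg1+/+. It was 5.40 and 6.48 against 1.53 and 2.84 in mTEChi, and 2.37 and 2.62 against 1.91 and 1.66 in mTEClo. After quantile and cyclic loess normalization the values closest to 0 were -0.31 and -0.35, which argues against the authors' scaling as the whole cause. A candidate explanation, held as a hypothesis found and tested on the same data, is that the standing of sort-specific regions over others depends in part on Brg1, but the few calls past the threshold do not show it: by limma 0 mTEChi-higher regions fell in mTEChi against 8 mTEClo-higher ones, and in mTEClo the 1 region that fell was mTEChi-higher, while at an unadjusted p under 0.05 mTEChi-higher regions leaned down in mTEChi (679 lower, 230 higher), mTEClo-higher ones leaned up there (562 lower, 953 higher) and mTEClo-higher ones leaned down in mTEClo (907 lower, 25 higher), with 8.62% and 3.30% of unchanged regions past that p in simulated mTEChi and mTEClo data. A difference between the mice or library batches of the Brg1 groups stays open. The descriptions of the Brg1+/+ libraries read NOCRE, so the groups may also differ in Cre, which was not separated from loss of Brg1. In mTEChi the call was lost without Brg1+/+ replicate 1, where the shift was -0.36.

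Aire-/- mTEChi had higher signal at mTEChi-higher regions by 0.21, which did not pass the test with an estimated correlation. Without the discordant Aire+/+ mTEChi replicate 2 the shift was 0.10, within the SD of 0.133 between libraries, and without replicate 1 of that group it was 0.30. The smaller of the shifts under quantile and cyclic loess normalization was 0.11, and against regions matched on signal the shift was 0.14 (SD 0.091). That library and the authors' scaling may therefore each account for part of the shift. An effect of Aire loss stays open as the biological explanation and was not separated from these.

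The limits of the chromosome 2 block were drawn from the wild types in mTEChi; in mTEClo, which did not set them, Aire+/+ lay below Brg1+/+ by a median log2 difference of -3.25, with an SD between libraries of 0.43, which argues against loss of Brg1 as its cause. In the knockout libraries, which did not set them either, the lowest of Brg1-/- lay above the highest of Aire-/- by 2.91 on the log2 scale, which argues against spread between libraries alone, though the labels do not give the number of mice and so whether all mice of each line differ in this way stays open. A candidate explanation is a difference in genomic copy number of the block between the mouse lines, which would raise nearly all regions in it in either sort: 98.8% of them were higher in each Brg1-/- library than in each Aire-/- library. Within the Brg1 cohort, the block was higher in Brg1-/- than in Brg1+/+ mTEChi by a median log2 of 0.80. Its library medians were 188.7 and 259.2 against 88.4 and 166.2, a difference that 1 copy number shared by the whole cohort would not give alone. In mTEClo the median log2 was 0.39, within the SD of 0.43 between libraries. The library medians there were 52.6 and 110.7 in Brg1-/- and 62.5 and 57.5 in Brg1+/+, so the groups overlapped. Within the Aire cohort, the median log2 fold change of Aire-/- against Aire+/+ in the block was -0.61 in mTEChi and -0.19 in mTEClo. Its library medians there were 4.30 to 8.45. A difference in chromatin that spans the block could raise its regions in the same way, so the 98.8% does not separate these explanations. The block held 106.1 regions per 100 kb, against 9.49 over the genome, and this was not tested. Genomic DNA was not analysed here, and a difference in chromatin between the lines that spans the block, or in the origin of this stretch, stays open, since all libraries are labelled C57BL/6 and the background of the lines is not described further.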

How the results depend on the processing

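The camera and fry tests of the class shifts, and the alternatives for these shifts by matched signal, knockout-derived classes and left-out libraries, for the overlap of the wild types, for the chromosome 2 block and for the median over all regions without a library were chosen after the data were seen; the others were planned.

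The count models were not run because the values are not counts. The gene lists with their alternatives and the genotype check were not run because no annotation of the build was used here, and the fit of a single cohort does not apply to the comparison of cohorts. Depth is unknown and limits what can be said of regions with low signal. Under alternatives, no named region changed direction. The 80 named between the sorts stayed past the threshold in all 1279 values, but those named for the knockouts often did not: 195 of 320 values were no longer past it for the 20 regions of Aire-/- mTEChi, 138 of 320 for the 20 of Brg1-/- mTEChi, 8 of 16 for the 1 of Brg1-/- mTEClo and 8 of 20 for the 1 of the Aire interaction. Where a result below changed, the cause was not tested, except that fewer libraries in a fit leave fewer degrees of freedom.

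Same-numbered libraries deviated from their group means with correlations of -0.018 to 0.034 over 12 pairs. No deviation shared by number was seen, but noise of single libraries could hide one, so pairing is not excluded. With a replicate block, Aire-/- mTEChi had 8 calls in place of 47, and Aire+/+ against Brg1+/+ had 164 in place of 352 in mTEChi and 51 in place of 83 in mTEClo; no other count moved by over 1.5 times.

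Calls in Aire-/- mTEChi (47) were 16 at a pseudocount of 0.5, 15 without the filter, 94 after quantile normalization, 16 after cyclic loess, 8 after re-centring, and by limma 0 with quality weights, with only the Aire cohort and with only the compared libraries. In Aire-/- mTEClo (0) they were 12 with quality weights, which are equal within each group here. Calls in Brg1-/- mTEChi (58) were 25 at a pseudocount of 5, 121 after quantile normalization (29 higher, 92 lower), 23 after cyclic loess (9 and 14), 8 with quality weights, 3 with only the Brg1 cohort and 0 with only the compared libraries. In Brg1-/- mTEClo (1) they were 12 with quality weights, 11 with only the compared libraries, and 0 at a pseudocount of 5, after quantile normalization and with only the cohort. The Aire interaction (1) was 0 at a pseudocount of 5, after quantile normalization, with only the cohort and with only the compared libraries. Beside these counts of 0, limma gave 22934, 5632, 24090, 13866 and 11603 regions at an unadjusted p under 0.05 in the fit of all libraries, in the order of these comparisons, where simulated data with no change put 8.03%, 1.09%, 8.62%, 3.30% and 4.25% of the 225281 regions there. After quantile normalization, 1 region rose in Aire-/- and fell in Brg1-/- mTEChi.

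Calls between the sorts were 9386 in Aire+/+ (19806), 42539 in Aire-/- (25604) and 11242 in Brg1-/- (18268) with only the compared libraries, 42492 in Aire-/- with quality weights, 17064 in Brg1+/+ (29209) and 9506 in Brg1-/- after quantile normalization, and 8431 in Brg1-/- after cyclic loess. Regions higher in mTEChi in both wild types (6746) were 3769, 4417 and 4107 after quantile, cyclic loess and re-centring. The correlation of the wild types' effects (0.589) was 0.637 at a pseudocount of 5 and 0.723 among regions at or above the median signal, and that of the Aire-/- and Brg1-/- effects (-0.088) was -0.067 after cyclic loess and -0.060 above the median signal. Calls between the cohorts are given here with those higher and lower in Aire+/+. With quality weights they were 91 in mTEChi (12 and 79) and 242 in mTEClo (107 and 135). They were 127 in mTEChi with only the compared libraries (2 and 125) and 150 in mTEClo after re-centring (2 and 148). Without the block they were 214 in mTEChi (147 and 67) and 7 in mTEClo (4 and 3). The block difference (-3.86 in mTEChi, -3.25 in mTEClo) was -3.26 and -2.53 at a pseudocount of 5, and -3.69 in mTEClo after re-centring.

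The medians over all regions went to near 0 after each rescaling, as these are built to do. After quantile normalization they were -0.0023 for Brg1-/- mTEChi, -0.020 for the Brg1 interaction, -0.017, -0.056, -0.0051 and -0.0072 between the sorts in Aire+/+, Aire-/-, Brg1+/+ and Brg1-/-, and -0.016 and -0.0045 between the cohorts in mTEChi and mTEClo. After cyclic loess they were -0.017, 0.0047, 0.00099 (Brg1+/+), 0.018 (Brg1-/-), 0.0036 and -0.019 in that order, and after re-centring -0.031, -0.0015, 0.025 (Aire+/+), 0.013 (Brg1+/+), 0.047 (Brg1-/-), 0.0034 and -0.022. Between the sorts of Brg1-/- the median was 0.48 at a pseudocount of 5 and 0.46 above the median signal, and between the cohorts in mTEClo it was 0.24 above the median signal.

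The Brg1-/- shift at mTEChi-higher regions in mTEChi was -0.23 against matched regions and otherwise -0.43 to -0.31 with all libraries. At mTEClo-higher regions in mTEChi, which did not pass, it was 0.044 after cyclic loess and 0.0053 above the median signal. The Brg1-/- shift at mTEClo-higher regions in mTEClo lay between -0.52 and -0.35 with all libraries. The Aire-/- shift at mTEClo-higher regions passed in mTEChi at -0.23 after cyclic loess and -0.21 above the median signal, and in mTEClo at -0.11 at a pseudocount of 5 (adjusted p = 0.0381), -0.13 above the median signal, -0.13 after cyclic loess and -0.10 with classes from Brg1-/-, with adjusted p from 0.0381 to 0.210 over the alternatives that keep all libraries and from 0.0411 to 0.246 without 1 library. The Aire interaction there, which did not pass, was 0.0013 at a pseudocount of 5, 9.2e-05 after re-centring and 0.026 with classes from Brg1-/-.

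Leaving out 1 library at a time gave 21 to 2243 calls in Aire-/- mTEChi, 0 to 25 in Aire-/- mTEClo, 101 to 340 in Brg1-/- mTEChi, 0 to 2 in Brg1-/- mTEClo, 0 to 73 and 0 to 7 for the Aire and Brg1 interactions, 6319 to 15244 (Aire+/+), 9021 to 12167 (Aire-/-), 11705 to 17031 (Brg1+/+) and 5945 to 9680 (Brg1-/-) between the sorts, and 282 to 1608 and 24 to 69 between the cohorts. Shared calls were 3025 to 4625 (mTEChi-higher) and 1550 to 3240 (mTEClo-higher) for the wild types, and 0 to 3, 0 to 2 and 0 to 1 for regions that rose in both knockouts, rose in Aire-/- and fell in Brg1-/-, and fell in Aire-/- and rose in Brg1-/-. Correlations were 0.485 to 0.591 for the wild types and -0.096 to -0.041 for the knockouts. The block difference was -4.31 to -3.41 in mTEChi and -3.45 to -2.69 in mTEClo. The median over all regions was 0.12 to 0.37 for Brg1-/- mTEChi and 0.52 to 0.78 between the sorts of Brg1-/-. Shifts were -0.46 to -0.36 for Brg1-/- mTEChi at mTEChi-higher regions, -0.58 to -0.45 for Brg1-/- mTEClo at mTEClo-higher regions, -0.074 to 0.011 for Aire-/- mTEClo at mTEChi-higher regions, and -0.25 to -0.051, -0.17 to -0.094 and -0.14 to 0.058 at mTEClo-higher regions for Aire-/- mTEChi, Aire-/- mTEClo and the Aire interaction. The extremes of Aire-/- mTEChi calls came without Aire-/- replicate 1 (21) and Aire+/+ replicate 1 (2243).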

Other observations

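The descriptions of clustering were planned, and the windows, which were ranked by their counts, were chosen after the data were seen. Regions that distinguish the sorts lay near one another more often than in shuffles over all tested regions. Of the regions higher in mTEChi in Aire+/+, 67.7% had another such region within 50 kb, against a mean of 54.0% in shuffles of the calls, and of those higher in mTEClo 52.4% did, against 43.7%. In Brg1+/+ the shares were 78.5% against 71.6% and 56.2% against 44.5% (permutation p = 0.001 for each, the smallest that 1000 shuffles can give, adjusted p = 0.002). None of the regions called in Aire-/- or Brg1-/- mTEChi had a call of the same direction within 50 kb, where shuffles gave means of 0.18% to 0.27%. In the comparison of the wild types, 68.3% of the regions lower in Aire+/+ mTEChi were so placed against 1.56% in shuffles; 138 of these 205 regions lay in the chromosome 2 block.

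Among windows of 1 Mb, the most regions higher in mTEChi in both wild types lay on chromosome 10 from 80000001 to 81000000, where 31 of 325 tested regions (9.54%) were called, against 2.99% of all regions. Chromosome 11 from 115000001 to 116000000 followed with 30 of 323, and chromosome 17 from 34000001 to 35000000 with 26 of 366. For regions higher in mTEClo, chromosome 13 from 60000001 to 61000000 held 13 of 137 (9.49%), against 1.77% of all regions. On chromosome X, 2.20% of regions were higher in mTEChi in Aire+/+ and 4.85% in Brg1+/+, against 5.14% and 9.21% of all regions; chromosome 11, with the highest shares, had 7.13% and 10.6%.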
